A study of Homo sapiens with 6 samples.

How the data were processed

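RNA of CAL-27 sphere cells was sequenced in 6 libraries, 3 titled CON and 3 titled LF3. Per the labels' protocols, total RNA was extracted with Trizol and libraries of circular single-stranded DNA, amplified as nanoballs, were read as single-end 50-base reads on a BGISEQ500 instrument. Whether RNA was selected by its poly(A) tail and whether the libraries kept strand are not given in the sources used here. The submitters' processing notes name HISAT, Bowtie2 and the build GRCm38.p6, with no versions for the tools. That build is a mouse assembly, while the identifiers and symbols of the deposited table are human, so no coordinates are printed and what the reads were aligned to is left open. Of the table's NCBI gene identifiers, 17222 (99.7%) were found in the human RefSeq gene table of GRCh38.p14, used for names only, and 16974 had the same symbol there; 17169 are protein coding.

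The deposited values are TPM per gene and library, written to 2 decimals, per the file's own values, which sum to the same total in every library. TPM divides each gene's reads by its length and scales the library to a fixed total, so a change in a few abundant genes moves all others, and the depth of each library is unknown. How reads matching several genes were counted is not given in the sources used here, so values of near-identical copies (histones, metallothioneins, HSPA1A and HSPA1B, ribosomal protein genes and their pseudogenes) and of overlapping or antisense neighbours are uncertain.

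Values were transformed to log2(TPM + 1), which understates the change of low genes. Genes with a mean of at least 1 TPM over the 6 libraries were tested (12195 of 17280, leaving 5085 untested). The LF3 libraries were compared with the CON libraries with limma 3.58.1 in R 4.3.3, using its moderated statistic with a mean-variance trend, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Replicate numbers were not used as a block. An exact permutation test of a single gene cannot give a p below 0.1 with 3 against 3, so none is given. Identical values made up 0.320 to 0.541% of tested genes between libraries of a group, and all 6 libraries were kept as separate samples. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

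Before the data were examined, 37 gene lists were fixed for the Wnt pathway, copper, stress, cell cycle, metabolism, cell identity, cell death and other cell types, along with the groups, the tests, the alternatives and the rule for named genes. Lists with at least 5 tested members (33 of them) were tested with camera at its preset correlation of 0.01. Camera asks whether the members of a list are shifted in a common direction relative to other genes. A list whose members changed in both directions can thus stay uncalled, and whether its members changed more than other genes was not tested. The alternatives were camera with an estimated correlation and fry. Lists overlap, since CD44, SLC7A11 and others stand in more than 1 list. The named genes are, in each direction, the 12 genes with the largest called change among genes with a mean of at least 5 TPM and groups that do not overlap; a fixed set of Wnt, copper and stemness genes; and up to 4 called members of each list with the smallest adjusted p. Not every gene that this rule picks is printed. After the data had been seen, 16 families were added by symbol pattern, of which 15 had at least 5 tested members; the patterns were then narrowed to leave out genes that share only a prefix, which brought the integrin and RAB families past the threshold.

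The whole procedure was tested on simulated data with known changes, on 12201 simulated genes that passed the filter for the comparison of LF3 with CON. It called 24% of genes changed by 0.25 on the log2 scale, 78% at 0.5, 95.9% at 1 and 100% at 2, each in the right direction, along with 11 unchanged genes (6.92% of its calls). It called the 1 list that was raised and 0 of 32 lists that were not. About 50 genes were changed at each size, with noise drawn separately for each gene. In the data 85.5% of tested genes were called, so these shares need not carry over. The simulated lists were random genes without shared noise, so they could not check the preset correlation. The alternatives were pseudocounts of 0.1 and 0.5, no filter, a filter of 5 TPM, median-ratio and quantile scaling, limma without a trend, with robust variances and with array weights, the replicate number as a block, and leaving out each library in turn.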

Results

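Gene expression was measured by RNA sequencing in 6 libraries of CAL-27, an established human line of tongue squamous cell carcinoma, grown as spheres, a floating culture used to enrich for cells with stem-like properties. The 3 control libraries are called CON. The other 3 libraries carry the title LF3, the name of a small molecule that blocks the binding of beta-catenin to TCF4 and with it the transcription of Wnt target genes, and the series design gives its exposure as 24 h. Their treatment field names something else, elesclomol with copper, a compound that carries copper into cells. The groups were taken from the titles, and each direction given is that of the libraries titled LF3 against CON. The comparison bears on how Wnt signalling in sphere cells relates to cuproptosis, a cell death driven by copper and tied to lipoylated enzymes of the mitochondrion. The deposited table holds 17280 genes in TPM, each gene's share of the transcripts corrected for its length, a unit that keeps no sequencing depth, so the depth behind each value is unknown and no counting interval was computed. No label says that the replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical. Gene values are means ± SD with n = 3 in each group, and log2 fold changes are LF3 minus CON on the log2(TPM + 1) scale, given ± their limma standard error.

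The LF3 libraries held more RNA of genes that build ribosomes, copy DNA and drive mitosis. They held less RNA of genes for glycolysis and the response to low oxygen, protein folding in the endoplasmic reticulum, cholesterol synthesis and replication-dependent histones. Camera called each of these lists at its preset correlation, and none held its call with an estimated correlation (adjusted p = 0.0574 to 0.188). The highest rise was that of CCL2, which encodes a monocyte-attracting chemokine, at 8.63 ± 1.01 TPM in CON and 1993 ± 142 TPM in LF3, a 231-fold ratio of means. The collagenase gene MMP1 fell from 606 ± 20.3 TPM in CON to 3.24 ± 0.872 TPM in LF3, and NDRG1, a gene induced by low oxygen, from 1974 ± 33.5 to 28.4 ± 2.03 TPM. Wnt target genes moved in both directions, with 9 higher and 7 lower among 16 tested (7 and 7 after rescaling the libraries).

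Of 12195 genes tested, 6489 were higher and 3938 lower in LF3 (limma, Benjamini-Hochberg adjusted p under 0.05), and 2540 and 1354 of them differed at least 2-fold. The values of the groups did not overlap in 10514 tested genes, 86.2% against the 10% that chance gives for 3 against 3. The median log2 fold change of all tested genes was 0.24, and rescaling each library by its median ratio to the gene-wise geometric mean brought it to -0.0055. The split then became 5195 higher and 5205 lower, so 62.2% of the called genes were higher as deposited and 50.0% after rescaling, or 51.4% after quantile normalization. The direction flipped between called values for 79 genes, so counts of list members are given with the counts after rescaling. Of 33 tested gene lists, camera called 6 higher and 10 lower, and with an estimated correlation 0 higher and 0 lower. The counts of called members adjusted over the list alone equalled those over all genes tested in all 33 lists. Pearson correlations of log2(TPM + 1) across genes, which are not independent replicates, were 0.996 to 0.997 within groups and 0.863 to 0.867 between them. The table listed 1391 ± 27.4 genes at 0 in CON and 1965 ± 19.4 in LF3. The 100 most abundant genes held 43.4 ± 0.266% of the TPM in CON and 33.5 ± 0.668% in LF3.

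**Figure D1:**
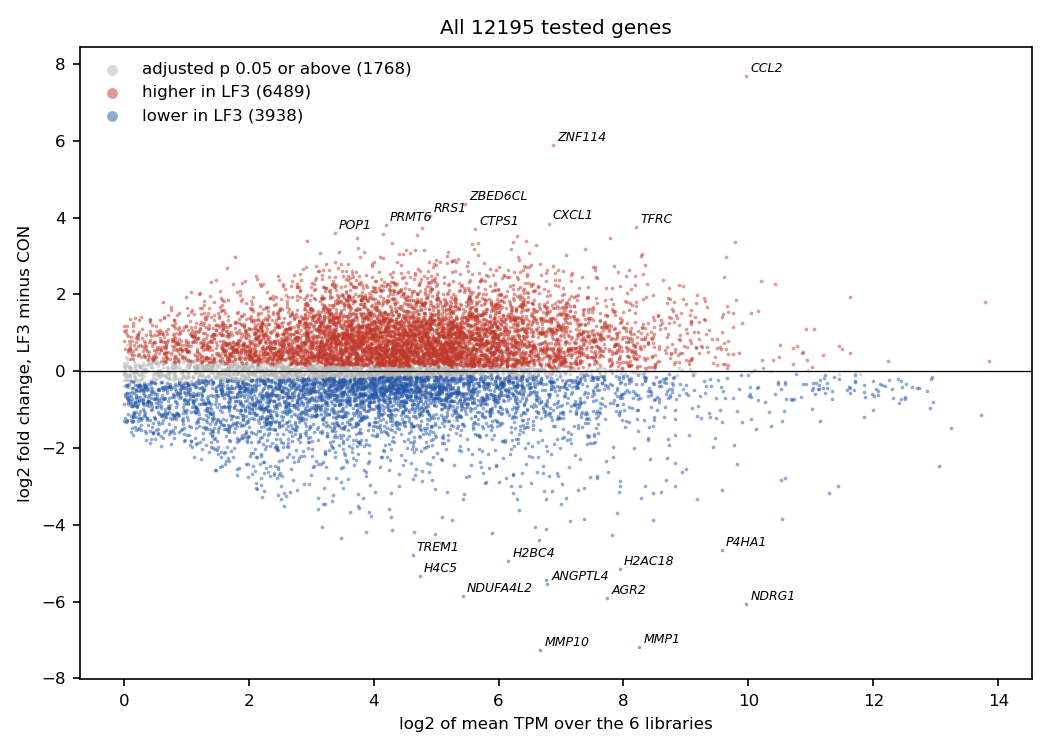
Each point is a tested gene, with the log2 of its mean TPM over the 6 libraries on the x axis and its log2 fold change, LF3 minus CON, on the y axis; red points were higher (6489), blue points lower (3938) and grey points not called (1768), and most genes of the naming rule are labelled. CCL2 stands highest at 7.70, and MMP10 and MMP1 lowest at -7.27 and -7.18, as deposited; the signs of these 3 genes held under both other scalings.

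Among the 12 genes with the largest rises at a mean of at least 5 TPM, 3 encode chemokines, and several others act in nucleotide, RNA and ribosome metabolism. Log2 fold changes were 7.70 ± 0.073 for CCL2, 3.85 ± 0.097 for CXCL1 and 3.57 ± 0.11 for CXCL2, the latter pair being attractants of neutrophils. The transferrin receptor gene TFRC, through which cells take up iron, stood at 39.4 ± 1.68 TPM in CON and 548 ± 25.5 TPM in LF3. Log2 fold changes were also 4.03 ± 0.064 for RRS1, 3.70 ± 0.049 for CTPS1, 3.60 ± 0.097 for POP1, 3.80 ± 0.068 for PRMT6, 3.55 ± 0.068 for TIMM8B and 3.73 ± 0.13 for GPATCH4. RRS1 acts in ribosome assembly, CTPS1 makes CTP, POP1 is a subunit of RNase P and RNase MRP, PRMT6 methylates arginine and TIMM8B acts in mitochondrial protein import. The remaining members were ZNF114 at 5.90 ± 0.059 and ZBED6CL at 4.35 ± 0.055.

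The 12 genes with the largest falls included secreted matrix proteases, genes of the hypoxic response and histones. MMP10 stood at 203 ± 8.46 TPM in CON and 0.343 ± 0.291 TPM in LF3. Log2 fold changes were -7.18 ± 0.11 for MMP1, -6.07 ± 0.048 for NDRG1, -5.55 ± 0.052 for ANGPTL4, -5.85 ± 0.096 for NDUFA4L2 and -4.65 ± 0.072 for P4HA1, of which ANGPTL4, NDUFA4L2 and the collagen prolyl hydroxylase P4HA1 are, like NDRG1, known to be induced by low oxygen. Of the histone genes, -5.44 ± 0.061 for H2BC21, -5.33 ± 0.28 for H4C5, -5.15 ± 0.043 for H2AC18 and -4.94 ± 0.30 for H2BC4 were in this group, all with near-identical copies elsewhere in the genome. AGR2, a protein disulfide isomerase of secretory cells, had a log2 fold change of -5.90 ± 0.085, and TREM1, a receptor of myeloid cells, one of -4.79 ± 0.23.

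Wnt target genes showed no common direction. The list had 9 of 16 tested members higher and 7 lower (7 and 7 after rescaling); its median was 0.45 and its mean 0.21 on the log2 scale, while camera, which compares the list with all other genes, gave a downward direction. Wnt targets gave a camera adjusted p = 0.840, and an adjusted p = 0.913 with an estimated correlation. Log2 fold changes above 0 were 3.09 ± 0.072 for DKK1, 1.27 ± 0.043 for CCND1, 1.21 ± 0.054 for MYC, 1.02 ± 0.081 for ZNRF3 and 0.40 ± 0.10 for TCF7, where DKK1 encodes a secreted Wnt antagonist, CCND1 cyclin D1 and ZNRF3 a ligase that removes Wnt receptors. The call of TCF7 was lost after median-ratio rescaling, where its log2 fold change was 0.18. The negative values were -1.80 ± 0.068 for SOX9, -1.23 ± 0.030 for CD44, -0.47 ± 0.13 for LEF1 and -0.23 ± 0.091 for RNF43; LEF1 lost its call under quantile normalization (adjusted p = 0.0710). The call of RNF43 (limma adjusted p = 0.0351; log2 fold change -0.28 to -0.14 when a library was left out) was lost without CON replicate 1, 2 or 3 (adjusted p = 0.0720, 0.0907 and 0.0566), without LF3 replicate 2 (adjusted p = 0.157) and with no filter (adjusted p = 0.0654). The direct feedback targets AXIN2, NKD1, SP5 and LGR5 lay below the filter of a mean of 1 TPM and were not tested. AXIN2 stood at 0.153 ± 0.0503 TPM in CON and 0.143 ± 0.0379 TPM in LF3, NKD1 at 0.730 ± 0.0557 TPM in CON and 0.717 ± 0.131 TPM in LF3 and SP5 at 0.807 ± 0.130 TPM in CON and 0.800 ± 0.0436 TPM in LF3, and LGR5 averaged 0.00500 TPM over the 6 libraries.

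Components of the Wnt pathway were likewise split. The list had 16 of 37 tested members higher and 9 lower (11 and 17 after rescaling), so its majority turned with the scaling. Wnt components gave a camera adjusted p = 0.835, and an adjusted p = 0.913 with an estimated correlation. The list's median was 0.13 (0.075 to 0.14 when a library was left out), and camera's direction was downward. Log2 fold changes were 1.13 ± 0.068 for LRP5, 0.86 ± 0.054 for PYGO2, -1.46 ± 0.054 for PORCN and -1.09 ± 0.044 for CSNK1E; LRP5 is a Wnt co-receptor, PYGO2 a nuclear partner of beta-catenin, PORCN the acyltransferase that Wnt ligands need for secretion and CSNK1E casein kinase 1 epsilon. CTNNB1, the beta-catenin gene, stood at 124 ± 2.43 TPM in CON and 147 ± 0.928 TPM in LF3 with a log2 fold change of 0.24 ± 0.035, which became -0.030 after median-ratio rescaling and -0.067 after quantile normalization. TCF7L2, which encodes TCF4, had 0.32 ± 0.084, with its call lost in both scalings (adjusted p = 0.356 and 0.0673).

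**Figure D2:**
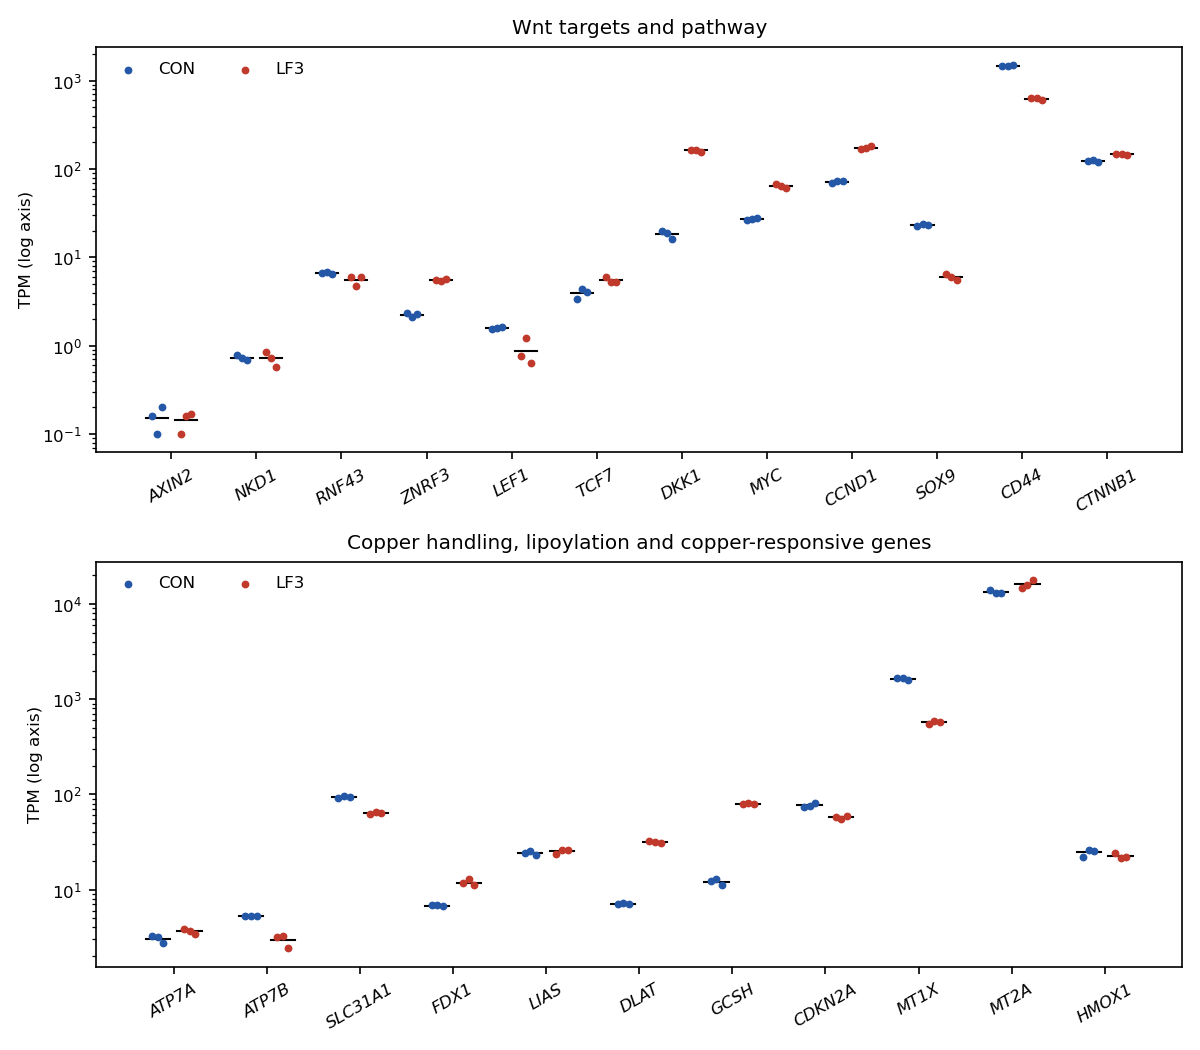
Points are the TPM of each library on a log axis, 3 CON libraries in blue and 3 LF3 libraries in red, with a black bar at each group's mean, for genes of the Wnt lists (top) and of the copper, lipoylation and copper-responsive lists (bottom). DKK1, MYC and CCND1 lie higher in all LF3 libraries and SOX9 and CD44 lower, AXIN2 lies near 0.153 TPM in CON and 0.143 TPM in LF3, and MT1X fell while the sign of CTNNB1, ATP7A, LIAS and MT2A depended on the scaling.

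Copper-handling genes were mostly higher, though not as a group beyond other genes. Of copper transport and chaperone genes, 12 of 19 tested members were higher and 4 lower (10 and 6 after rescaling). Copper transport genes gave a camera adjusted p = 0.260, and an adjusted p = 0.427 with an estimated correlation. The copper importer gene SLC31A1 stood at 94.2 ± 2.63 TPM in CON and 63.5 ± 1.09 TPM in LF3, and the copper exporter gene ATP7B at 5.27 ± 0.0513 TPM in CON and 2.96 ± 0.487 TPM in LF3, both called lower (limma adjusted p = 1.84e-07 and 9.15e-05). The other exporter gene, ATP7A, had 0.20 ± 0.092 (adjusted p = 0.0601), was -0.0084 after median-ratio rescaling and passed the threshold under quantile normalization (0.22, adjusted p = 0.0375) and without LF3 replicate 3 (0.24, adjusted p = 0.0477). ATP7A also passed without a trend (adjusted p = 0.0238) and with array weights (adjusted p = 0.0474). Higher values were 1.55 ± 0.074 for SCO1, 1.38 ± 0.036 for SLC25A3, 1.27 ± 0.032 for SOD1 and 1.22 ± 0.053 for COX11, genes that supply copper to cytochrome c oxidase (SCO1, COX11), carry phosphate and copper into mitochondria (SLC25A3) or encode the copper-zinc superoxide dismutase (SOD1). MTF1, the metal-sensing transcription factor, had -0.19 ± 0.066, and its call was lost without CON replicate 2 (adjusted p = 0.0739).

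Genes of the lipoylation pathway that cuproptosis acts on were in part higher. Their list had 10 of 17 tested members higher and 4 lower (8 and 6 after rescaling). The lipoylation list gave a camera adjusted p = 0.417, and an adjusted p = 0.747 with an estimated correlation. GCSH, the lipoyl carrier of the glycine cleavage system, stood at 12.1 ± 0.935 TPM in CON and 79.5 ± 1.39 TPM in LF3, and DLAT, the lipoylated core of pyruvate dehydrogenase, at 7.08 ± 0.125 TPM in CON and 31.4 ± 0.779 TPM in LF3. Log2 fold changes were 1.28 ± 0.049 for DLD, 0.97 ± 0.047 for PDHA1 and 0.72 ± 0.073 for FDX1, FDX1 being the ferredoxin that reduces elesclomol-bound copper. The lipoyl synthase gene LIAS had 0.056 ± 0.061 (adjusted p = 0.403; log2 fold change 0.024 to 0.098 when a library was left out), and it was called lower after median-ratio rescaling (-0.21) and quantile normalization (-0.27). CDKN2A had -0.42 ± 0.051. Iron-sulfur cluster assembly genes were higher: 16 of 20 tested members were higher and 2 lower (14 and 4 after rescaling), with 1.47 ± 0.034 for HSPA9, 1.17 ± 0.055 for CIAO1, 1.03 ± 0.050 for GLRX5 and 0.93 ± 0.042 for BOLA3. Iron-sulfur genes gave a camera adjusted p = 0.0311, and an adjusted p = 0.267 with an estimated correlation. That list's call was also lost after both scalings (adjusted p = 0.0628 and 0.105) and with a filter of 5 TPM (adjusted p = 0.0700).

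Metallothioneins, which bind copper and zinc and are induced by both, moved in both directions. In their list, 2 of 6 tested members were higher and 2 lower (1 and 3 after rescaling), with a median of 0.16 (0.11 to 0.18 when a library was left out), a mean of -0.32 and a downward direction by camera. The metallothionein list gave a camera adjusted p = 0.589, and an adjusted p = 0.747 with an estimated correlation. MT1X stood at 1641 ± 54.2 TPM in CON and 576 ± 19.9 TPM in LF3 and MT1E at 2152 ± 51.7 TPM in CON and 3424 ± 138 TPM in LF3. Changes on the log2 scale were -1.51 ± 0.036 for MT1X, 0.67 ± 0.034 for MT1E and -1.66 ± 0.12 for MT1F, and these paralogs share near-identical stretches of sequence. MT2A, the most abundant of them at 13374 ± 647 TPM in CON and 16104 ± 1654 TPM in LF3, had 0.26 ± 0.062, which became -0.010 after median-ratio rescaling and 0.57 after quantile normalization. MT1E had 0.40 and 0.99 under these scalings, and the list's median was -0.10 and -0.11. The heme oxygenase gene HMOX1 stood at 24.6 ± 2.05 TPM in CON and 22.5 ± 1.61 TPM in LF3 (-0.12 ± 0.074, limma adjusted p = 0.155; log2 fold change -0.19 to -0.080 when a library was left out); it was called lower after median-ratio rescaling (-0.38), quantile normalization (-0.44) and without CON replicate 1 (-0.19). Cytosolic heat shock genes were higher, as 16 of 21 tested members were higher and 5 lower (15 and 5 after rescaling). Heat shock genes gave a camera adjusted p = 0.0196, and an adjusted p = 0.599 with an estimated correlation. Values were 3.37 ± 0.030 for HSPA8, 2.46 ± 0.030 for HSPE1, 1.67 ± 0.030 for STIP1, 1.63 ± 0.035 for AHSA1 and 0.55 ± 0.049 for HSPA1A; HSPA1A shares reads with its near-identical copy HSPA1B. NRF2 antioxidant targets had 16 of 25 tested members higher and 6 lower (15 and 8 after rescaling), with 1.81 ± 0.030 for FTH1, 1.78 ± 0.050 for TALDO1, 1.72 ± 0.052 for NQO1 and 1.58 ± 0.039 for TXN. NRF2 targets gave a camera adjusted p = 0.207, and an adjusted p = 0.691 with an estimated correlation. Their list passed the threshold only with no filter among the camera settings run (adjusted p = 0.0485).

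Cell cycle and ribosome production genes were higher throughout their lists. DNA replication genes had 34 of 34 tested members higher and 0 lower (33 and 0 after rescaling) with a median log2 fold change of 1.92. Replication genes gave a camera adjusted p = 1.14e-08, and an adjusted p = 0.0574 with an estimated correlation. PCNA, the sliding clamp of DNA polymerase, stood at 58.7 ± 3.60 TPM in CON and 400.1 ± 2.08 TPM in LF3, and log2 fold changes were 3.34 ± 0.049 for UHRF1, 2.83 ± 0.048 for MCM6 and 2.77 ± 0.047 for MCM3. Among mitosis genes, 30 of 30 tested members were higher and 0 lower (30 and 0 after rescaling), with a median of 1.68. Mitosis genes gave a camera adjusted p = 1.30e-07, and an adjusted p = 0.0896 with an estimated correlation. The kinase gene PLK1 stood at 13.7 ± 0.764 TPM in CON and 134 ± 7.33 TPM in LF3, and values were 2.72 ± 0.042 for CCNB1, 2.70 ± 0.048 for CDC20 and 2.13 ± 0.045 for BIRC5. For ribosome biogenesis, 25 of 25 tested members were higher and 0 lower (25 and 0 after rescaling), with a median of 2.20. Ribosome biogenesis genes gave a camera adjusted p = 1.89e-07, and an adjusted p = 0.0574 with an estimated correlation. The nucleolar genes NOP16, NOP56 and NCL had 3.28 ± 0.057, 2.55 ± 0.045 and 2.27 ± 0.036. No tested list held its call with an estimated correlation, where the lowest adjusted p was 0.0574 and 8 lists had an unadjusted p under 0.05; fry, which does not compare a list with other genes, called 30 lists.

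Genes for the proteins of the cytosolic ribosome and for replication-dependent histones went the other way. Cytosolic ribosomal protein genes had 0 of 57 tested members higher and 54 lower (0 and 57 after rescaling), with a median of -0.40, and quantile normalization gave a median of -0.15 without a call (adjusted p = 0.0714). Ribosomal protein genes gave a camera adjusted p = 2.73e-14, and an adjusted p = 0.121 with an estimated correlation. Log2 fold changes were -0.81 ± 0.027 for RPS18, -0.74 ± 0.029 for RPL10 and -0.62 ± 0.024 for RPL12 (-0.22, -0.68 and -0.15 after quantile normalization), and many of these genes have processed pseudogenes. Of the replication-dependent histone genes, 0 of 13 tested members were higher and 12 lower (0 and 12 after rescaling), with a median of -3.45. Histone genes gave a camera adjusted p = 2.58e-06, and an adjusted p = 0.0896 with an estimated correlation. The linker histone gene H1-2 stood at 667 ± 9.13 TPM in CON and 44.5 ± 2.50 TPM in LF3, and values were -3.45 ± 0.054 for H2BC5 and -2.47 ± 0.074 for H2AC6.

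Genes of glycolysis and the hypoxic response were mostly lower. The list had 5 of 33 tested members higher and 28 lower (1 and 28 after rescaling), with a median of -1.76. Hypoxia and glycolysis genes gave a camera adjusted p = 5.83e-11, and an adjusted p = 0.0896 with an estimated correlation. HK2, a hexokinase at the entry of glycolysis, stood at 567 ± 2.91 TPM in CON and 56.5 ± 1.59 TPM in LF3, and log2 fold changes were -6.07 ± 0.048 for NDRG1, -3.33 ± 0.037 for ALDOC and -3.17 ± 0.038 for ENO2. Nuclear-encoded respiratory chain genes were higher, as 46 of 55 tested members were higher and 2 lower (38 and 13 after rescaling), with a median of 0.59. Respiratory chain genes gave a camera adjusted p = 6.73e-05, and an adjusted p = 0.113 with an estimated correlation. The ATP synthase and complex I genes named by the rule had 1.79 ± 0.039 for ATP5MC1, 1.59 ± 0.037 for ATP5MC3, 1.15 ± 0.027 for ATP5F1B and 1.54 ± 0.035 for NDUFS6. Citric acid cycle genes had 14 of 19 tested members higher and 2 lower (12 and 5 after rescaling), with 1.71 ± 0.041 for FH, 1.17 ± 0.039 for SUCLG1, 1.12 ± 0.037 for IDH3B and 0.97 ± 0.037 for SDHB. Citric acid cycle genes gave a camera adjusted p = 0.0572, and an adjusted p = 0.255 with an estimated correlation. Their list passed the threshold with no filter (adjusted p = 0.00844) and without LF3 replicate 1 (adjusted p = 0.0499). None of the 13 mitochondrially encoded genes has a row in the table used here.

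Secretory and sterol genes were lower. In the list of the unfolded protein response of the endoplasmic reticulum, 3 of 21 tested members were higher and 17 lower (2 and 18 after rescaling), with a median of -1.16. Unfolded protein response genes gave a camera adjusted p = 6.67e-07, and an adjusted p = 0.188 with an estimated correlation. HSPA5, the main chaperone of this compartment, stood at 4497 ± 2.46 TPM in CON and 500.2 ± 14.3 TPM in LF3, and values were -3.00 ± 0.048 for HSP90B1, -2.64 ± 0.042 for HERPUD1 and -1.96 ± 0.034 for PDIA4. Cholesterol synthesis genes had 3 of 24 tested members higher and 20 lower (3 and 21 after rescaling), with a median of -1.17. Cholesterol synthesis genes gave a camera adjusted p = 3.40e-07, and an adjusted p = 0.121 with an estimated correlation. INSIG1, which holds back sterol synthesis when sterols are ample, had -3.14 ± 0.040, and the pathway enzymes MSMO1, HMGCS1 and SQLE had -2.99 ± 0.056, -2.62 ± 0.045 and -2.24 ± 0.037. ATF4 targets went both ways, as 12 of 29 tested members were higher and 16 lower (8 and 17 after rescaling). ATF4 targets gave a camera adjusted p = 0.0494, and an adjusted p = 0.427 with an estimated correlation. The stress regulators DDIT3, ATF3 and DDIT4 had -2.75 ± 0.037, -2.98 ± 0.045 and -1.74 ± 0.039, while the amino acid transporter SLC7A5 had 1.88 ± 0.037. The ATF4 call was lost after both scalings (adjusted p = 0.0751 and 0.0642), without CON replicate 3 (adjusted p = 0.0513) and without LF3 replicate 2 (adjusted p = 0.0574). It was also lost with a pseudocount of 0.1 (adjusted p = 0.0514) and with the replicate block (adjusted p = 0.0645). With no filter and with a filter of 5 TPM the ATF4 median moved from -0.36 to -0.20, without a call (adjusted p = 0.118 and 0.0700).

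**Figure D3:**
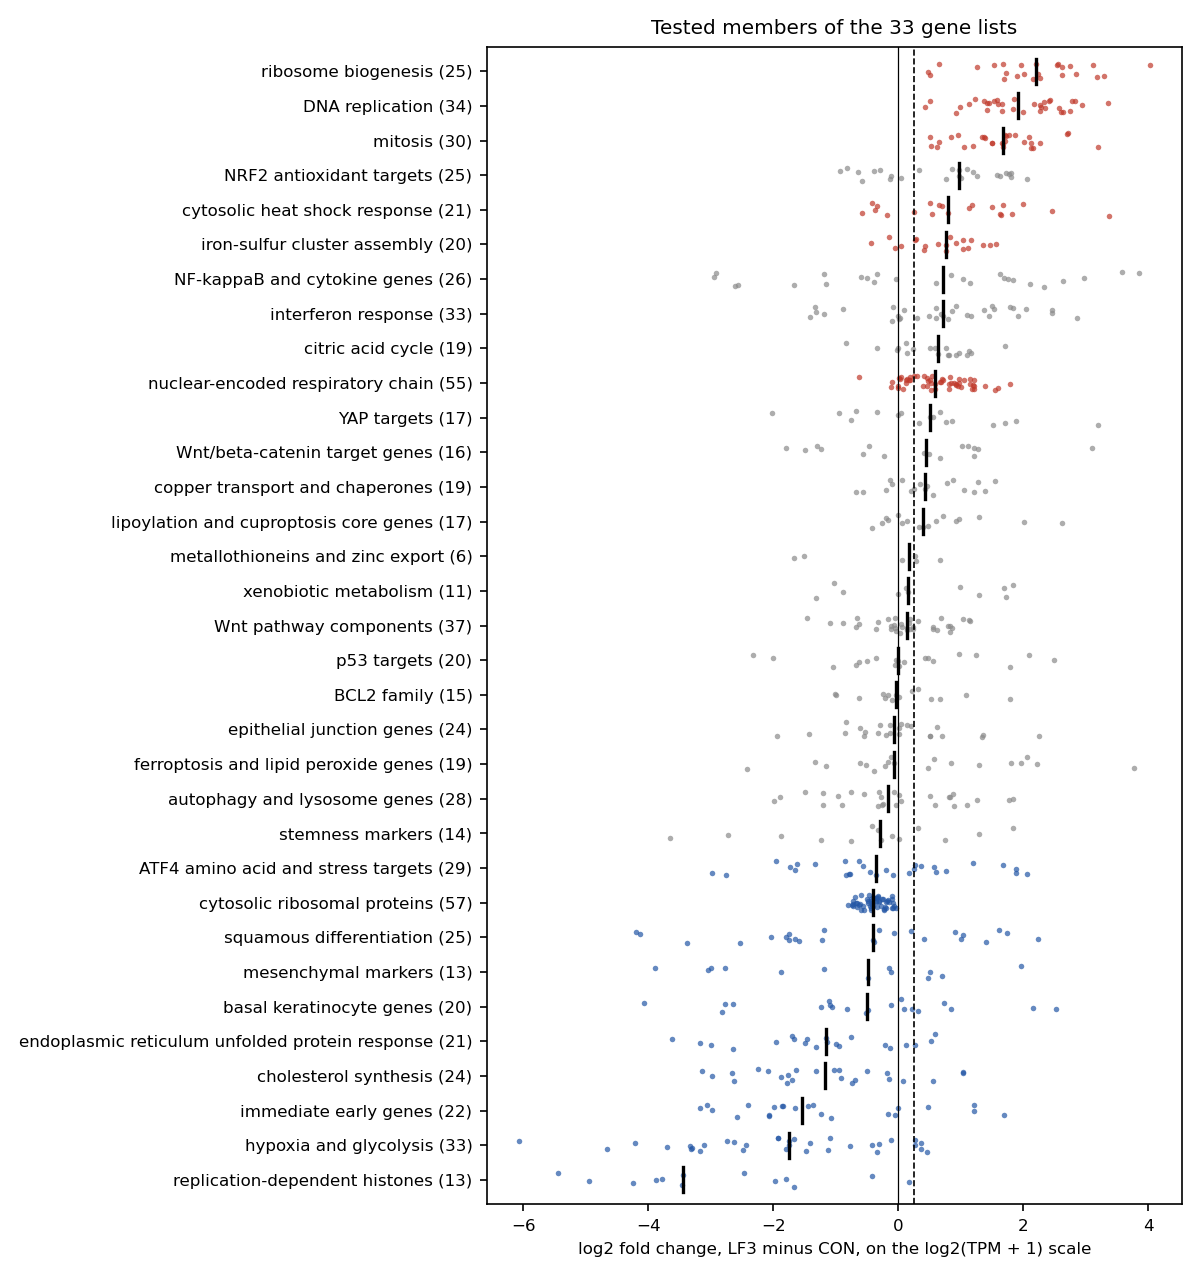
Each point is a tested member of 1 of the 33 tested lists (number of members in brackets), with its log2 fold change, LF3 minus CON, on the x axis; the black bar is the list's median, the dashed line the median of all tested genes (0.24), and red and blue mark lists called higher (6) and lower (10) by camera with its preset correlation, none of which held with an estimated correlation. List medians run from -3.45 for replication-dependent histones to 2.20 for ribosome biogenesis as deposited, and rescaling turned the sign of the median of Wnt pathway components, metallothioneins and xenobiotic metabolism.

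Immediate early genes, which growth and stress signals switch on within minutes, were mostly lower. Their list had 4 of 22 tested members higher and 16 lower (4 and 18 after rescaling), with a median of -1.54. Immediate early genes gave a camera adjusted p = 5.06e-05, and an adjusted p = 0.267 with an estimated correlation. The AP-1 gene JUN stood at 226 ± 6.89 TPM in CON and 61.3 ± 2.68 TPM in LF3, and the phosphatases DUSP5 and DUSP6 had -1.99 ± 0.042 and -2.07 ± 0.047. NF-kappaB and cytokine genes were split, as 14 of 26 tested members were higher and 11 lower (14 and 12 after rescaling), with a median of 0.72 and a downward direction by camera. NF-kappaB and cytokine genes gave a camera adjusted p = 0.840, and an adjusted p = 0.920 with an estimated correlation. Values were 2.97 ± 0.056 for SOD2 and 2.63 ± 0.048 for TNFAIP2 on the higher side and -2.94 ± 0.052 for SAA2 and -2.56 ± 0.033 for LCN2 on the lower side. Interferon response genes had 22 of 33 tested members higher and 5 lower (21 and 10 after rescaling), passing the threshold with no filter (adjusted p = 0.0248). The antiviral genes IFIT3, IFIT2 and OAS3 had 2.85 ± 0.10, 2.46 ± 0.086 and 1.79 ± 0.052, and BST2 had -1.19 ± 0.048. Interferon response genes gave a camera adjusted p = 0.175, and an adjusted p = 0.691 with an estimated correlation.

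Markers of stem-like and mesenchymal cells were more often lower than higher. Stemness markers had 4 of 14 tested members higher and 8 lower (3 and 10 after rescaling), and the list was not called. Stemness markers gave a camera adjusted p = 0.0737, and an adjusted p = 0.427 with an estimated correlation. The surface antigen CD44 stood at 1476 ± 20.2 TPM in CON and 627 ± 16.0 TPM in LF3. Values were -3.66 ± 0.11 for NGFR, -2.72 ± 0.093 for CD24 and -0.42 ± 0.12 for ALDH1A1 on the lower side and 1.29 ± 0.054 for ALDH1A3 and 0.75 ± 0.12 for BMI1 on the higher side. SOX2 lay below the filter at 0.563 ± 0.0473 TPM in CON and 1.39 ± 0.419 TPM in LF3. Mesenchymal markers had 4 of 13 tested members higher and 9 lower (4 and 9 after rescaling), with a median of -0.48 (-0.54 to -0.26 when a library was left out). Mesenchymal markers gave a camera adjusted p = 0.0250, and an adjusted p = 0.480 with an estimated correlation. Fibronectin gene FN1 stood at 295 ± 4.89 TPM in CON and 34.8 ± 1.57 TPM in LF3, and ITGA5 had -2.99 ± 0.039. The mesenchymal list's call was lost after both scalings (adjusted p = 0.0557 and 0.0509).

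Epithelial identity genes were divided. Of basal keratinocyte genes, 6 of 20 tested members were higher and 11 lower (4 and 14 after rescaling), with a median of -0.50; KRT15 and the laminin gene LAMB3 had -4.06 ± 0.048 and -2.83 ± 0.039, while the caveolin gene CAV1 had 2.53 ± 0.039. Basal keratinocyte genes gave a camera adjusted p = 0.0196, and an adjusted p = 0.599 with an estimated correlation. Squamous differentiation genes had 9 of 25 tested members higher and 15 lower (8 and 15 after rescaling), with a median of -0.41, and values were -3.38 ± 0.11 for RHCG, -2.03 ± 0.061 for ECM1, -1.75 ± 0.042 for KRT17 and 1.74 ± 0.045 for KRT80. Squamous genes gave a camera adjusted p = 0.0482, and an adjusted p = 0.396 with an estimated correlation. The squamous call was lost after both scalings (adjusted p = 0.146 and 0.181), without CON replicate 2 (adjusted p = 0.0638) and without CON replicate 3, where the median moved to -0.74 (adjusted p = 0.0513). With a filter of 5 TPM the squamous median moved to -0.10 and the call was lost (adjusted p = 0.244), as it was with a pseudocount of 0.1 (adjusted p = 0.0588) and with the replicate block (adjusted p = 0.0542). Epithelial junction genes had 9 of 24 tested members higher and 12 lower (7 and 16 after rescaling), with 2.25 ± 0.072 for ESRP2, 1.35 ± 0.073 for CLDN1, -1.94 ± 0.070 for PKP1 and -1.42 ± 0.065 for CLDN7. Epithelial junction genes gave a camera adjusted p = 0.260, and an adjusted p = 0.747 with an estimated correlation.

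Cell death and survival lists were not called. For p53 targets, 8 of 20 tested members were higher and 7 lower (8 and 11 after rescaling), with a median of -0.0011 (-0.018 to 0.031 when a library was left out) and a mean of 0.12; the cell cycle inhibitor CDKN1A had -2.01 ± 0.037 and TP53INP1 -2.33 ± 0.076, against 2.50 ± 0.075 for AEN and 1.79 ± 0.055 for BAX. The sign of the p53 median also turned with the library left out. p53 targets gave a camera adjusted p = 0.556, and an adjusted p = 0.747 with an estimated correlation. The BCL2 family had 6 of 15 tested members higher and 6 lower (4 and 9 after rescaling), with a median of -0.039 (-0.085 to -0.014 when a library was left out) and a mean of 0.079, and values were 0.66 ± 0.044 for BID and -1.02 ± 0.095 for BCL2A1, with BMF called lower as well. BCL2 family genes gave a camera adjusted p = 0.566, and an adjusted p = 0.691 with an estimated correlation. Ferroptosis genes had 9 of 19 tested members higher and 7 lower (9 and 10 after rescaling), with a median of -0.073 (-0.10 to 0.010 when a library was left out, so its sign turned) and a mean of 0.42, where 1.96 ± 0.070 for LPCAT3 and -2.42 ± 0.028 for SAT1 lay on opposite sides. Ferroptosis genes gave a camera adjusted p = 0.835, and an adjusted p = 0.913 with an estimated correlation. YAP targets had 10 of 17 tested members higher and 5 lower (9 and 7 after rescaling), with 3.19 ± 0.049 for FJX1, 1.88 ± 0.038 for F3, 1.51 ± 0.048 for AJUBA and -2.02 ± 0.059 for GADD45B. YAP targets gave a camera adjusted p = 0.589, and an adjusted p = 0.691 with an estimated correlation. Autophagy and lysosome genes had 10 of 28 tested members higher and 14 lower (10 and 17 after rescaling), with 1.25 ± 0.044 for GLA, -1.98 ± 0.059 for ULK1 and -1.21 ± 0.039 for NEU1. Autophagy genes gave a camera adjusted p = 0.147, and an adjusted p = 0.427 with an estimated correlation. Xenobiotic metabolism genes had 5 of 11 tested members higher and 3 lower (5 and 3 after rescaling), with 0.98 ± 0.049 for ABCC1 and -1.03 ± 0.044 for TIPARP. Xenobiotic metabolism genes gave a camera adjusted p = 0.835, and an adjusted p = 0.913 with an estimated correlation.

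Markers of other cell types had too few tested members for a list test. All 4 tested fibroblast markers were lower (4 after rescaling), with -0.95 ± 0.080 for COL1A1, -1.12 ± 0.12 for LUM, -0.96 ± 0.12 for ACTA2 and -0.29 ± 0.11 for PDGFRB. PDGFRB lost its call under quantile normalization (adjusted p = 0.117), without CON replicate 2 (adjusted p = 0.0909) and without LF3 replicate 2 (adjusted p = 0.102). Among 4 tested leukocyte markers, 1 was higher and 3 lower (1 and 3 after rescaling). The lysosomal antigen CD68, which many cell types express, stood at 334 ± 6.49 TPM in CON and 47.4 ± 2.25 TPM in LF3. Other values were -1.22 ± 0.077 for CSF1R, -0.51 ± 0.13 for ITGAM and 0.82 ± 0.13 for CD14, with ITGAM losing its call under quantile normalization (adjusted p = 0.0579). The single tested endothelial marker, CDH5, stood at 0.110 ± 0 TPM in CON and 6.19 ± 0.654 TPM in LF3.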

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

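Called genes numbered 6236 to 6550 higher and 3749 to 3937 lower when each library was left out in turn, and lists 6 to 7 higher and 8 to 10 lower. Among 173 named and tested genes, 160 kept direction and side of the threshold in every alternative in which they were tested; among 33 lists, 3 did and 27 kept camera's direction, and among 15 families, chosen after seeing the data, 2 did and 14 kept it. The directions given by fry are counted in these figures for lists and families. Quantile normalization left 6 lists lower. With an estimated correlation camera called 0 lists higher and 0 lower, and fry called 18 higher and 12 lower; fry tests a list's own balance, not its standing among other genes. These alternatives did not test the cause of the changes.

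The replicate numbers are shared between the groups. Correlations of deviations between libraries of the same number were 0.048, 0.11 and 0.16 for numbers 1, 2 and 3, not all above 0.1. CON replicate 1 correlated more with LF3 replicate 2 (0.074), so the numbers were not taken as pairs. All remaining pairs of unlike number across the groups had negative values (-0.17 to -0.013), so a weak pairing stays possible. With the replicate block, 6536 genes were higher and 3986 lower, with 6 lists higher and 8 lower; the ATF4 and squamous differentiation lists lost their calls (adjusted p = 0.0645 and 0.0542), and no other named call changed.

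The results listed next had a test direction opposite to the main one, and the list's median log2 fold change, which often kept its sign, is given. Fry gives the direction of the list itself and camera that relative to other genes. A difference between fry and camera is thus not a reversal of the same measure. For NF-kappaB genes the median was 0.47 with no filter, 0.45 after median-ratio and 0.39 after quantile scaling, and 0.72 with fry. Wnt targets had 0.25 and 0.50 after these scalings and 0.45 with fry, and ferroptosis genes -0.34, 0.043 and -0.073. The direction given by fry also differed for Wnt components (0.13) and the BCL2 family (-0.039), and a filter of 5 TPM reversed camera's direction for xenobiotic metabolism (0.15). The ZNF family, chosen after seeing the data, reversed with no filter, with no trend and with fry (0.21 each), after quantile normalization (0.10) and without LF3 replicate 3 (0.26); leaving out each library gave ZNF medians of 0.19 to 0.26. After median-ratio scaling the log2 fold change was -0.030 for CTNNB1, -0.0084 for ATP7A, -0.21 for LIAS and -0.010 for MT2A; quantile normalization gave -0.067 for CTNNB1 and -0.27 for LIAS. TPM holds no depth, so what depth limits could not be measured. In the simulation, where few genes changed, a change of 0.25 on the log2 scale was called in 24% of genes. That share need not hold for these data.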

Other observations

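Families picked by symbol after seeing the data extended both sides of the comparison. Proteasome subunits, which degrade ubiquitin-tagged proteins, had 36 of 37 tested members higher and 0 lower (36 and 1 after rescaling) with a median log2 fold change of 1.59, and mitochondrial ribosomal proteins had 76 of 78 tested members higher and 2 lower (69 and 2 after rescaling) with a median of 0.98. Proteasome genes gave a camera adjusted p = 1.50e-09, and an adjusted p = 0.0124 with an estimated correlation. Mitochondrial ribosomal genes gave a camera adjusted p = 2.12e-09, and an adjusted p = 0.0124 with an estimated correlation. PSMD1 stood at 39.6 ± 0.910 TPM in CON and 211 ± 4.72 TPM in LF3 and MRPL12 at 42.1 ± 3.02 TPM in CON and 245 ± 5.47 TPM in LF3; genes named in these family sentences were chosen after their values were seen. The chaperonin CCT had 9 of 9 subunits higher (camera adjusted p = 0.000894, and an adjusted p = 0.171 with an estimated correlation), nucleoporins 20 of 21 (camera adjusted p = 4.51e-05, and an adjusted p = 0.150 with an estimated correlation), aminoacyl-tRNA synthetases 33 of 36 (camera adjusted p = 4.51e-05, and an adjusted p = 0.115 with an estimated correlation) and DEAD and DEAH box helicases 45 of 51 (camera adjusted p = 1.25e-05, and an adjusted p = 0.150 with an estimated correlation). RNA polymerase subunits had 26 of 33 higher (camera adjusted p = 0.00384, and an adjusted p = 0.0771 with an estimated correlation), mitochondrial import proteins 21 of 24 (camera adjusted p = 0.00123, and an adjusted p = 0.0752 with an estimated correlation) and snRNP and LSM proteins 21 of 24 (camera adjusted p = 0.000743, and an adjusted p = 0.0752 with an estimated correlation); the majority of each of these 9 families stayed higher after rescaling.

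Matrix and adhesion families lay on the other side. Collagen chains had 4 of 22 tested members higher and 15 lower (2 and 18 after rescaling), with COL6A2 at 118 ± 5.78 TPM in CON and 28.5 ± 1.52 TPM in LF3. Collagen chains gave a camera adjusted p = 0.000758, and an adjusted p = 0.209 with an estimated correlation. Matrix metalloproteinases had 2 of 9 tested members higher and 6 lower (1 and 6 after rescaling). Matrix metalloproteinases gave a camera adjusted p = 0.00746, and an adjusted p = 0.188 with an estimated correlation. Integrin subunits had 5 of 17 tested members higher and 10 lower (3 and 13 after rescaling), and their call was lost with a filter of 5 TPM (adjusted p = 0.0605). Integrin subunits gave a camera adjusted p = 0.0194, and an adjusted p = 0.326 with an estimated correlation. RAB GTPases, which direct membrane traffic, had 20 of 52 tested members higher and 24 lower (12 and 31 after rescaling), and that call was lost with no filter (adjusted p = 0.169) and without LF3 replicate 1 (adjusted p = 0.0520). RAB genes gave a camera adjusted p = 0.0458, and an adjusted p = 0.326 with an estimated correlation. Chemokines had 7 of 14 tested members higher and 5 lower (6 and 6 after rescaling), without a call (camera adjusted p = 0.796, and an adjusted p = 0.818 with an estimated correlation). Zinc finger ZNF genes had 162 of 321 tested members higher and 82 lower (124 and 121 after rescaling), also without a call (camera adjusted p = 0.938, and an adjusted p = 0.979 with an estimated correlation).

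Of the explanations weighed here, the test of copper exposure and the count of other splits were fixed before the data were examined, and the tests of scaling, exchanged titles, histone copies, cycling cells and poly(A) tails were chosen after the results they measure had been seen. The titles say LF3 and the treatment field says elesclomol with copper. Copper brought in by elesclomol would be predicted to raise metallothioneins by more than 1 on the log2 scale together with HMOX1 and HSPA1A, and the median over 6 tested metallothionein and zinc export genes was 0.16 (0.11 to 0.18 when a library was left out), below the bound of 0.5 set beforehand. As deposited no member rose by more than 0.67. After quantile normalization MT1E had 0.99, close to the predicted rise, and MT2A 0.57, while the list's median was -0.11. MT1X fell, and HMOX1 was below 0 in every setting. The summed TPM of 6 MT1 and MT2 genes was a measure added after seeing the data. These genes were picked by symbol, without the filter and without the zinc export gene, so they need not be the 6 tested list members. It was 17229.5 ± 718 in CON and 20130.3 ± 1799.9 in LF3 (log2 ratio 0.22, 0.038 to 0.39 over pairs of libraries). Most of that sum was MT2A (13374 TPM in CON and 16104 TPM in LF3), and the sum was not rescaled. Together these values argue against a copper response of that size across the list and HMOX1 at this time. A smaller, earlier or partial response stays open, since members went both ways and MT1E and MT2A depended on the scaling. MT2A was also already abundant in CON, and HSPA1A was higher (0.27 and 0.30 after the scalings). The heat shock list was higher too, with a camera adjusted p = 0.0196, and an adjusted p = 0.599 with an estimated correlation. Whether LF3 itself acted is not shown either. Only 1 of the 10 splits of the 6 libraries, the real one, gave as many called genes (10427 against a highest other count of 0). With 10 splits the share cannot fall under 0.05. Each other split also put libraries of both titles on both sides, where the difference between the titles becomes spread within a side. Low counts there were set beforehand, so the contrast does not measure chance.

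Lower hypoxia and glycolysis genes beside higher replication and mitosis genes form the second pattern, though these list calls were lost with an estimated correlation (adjusted p = 0.0896, 0.0574 and 0.0896). A shift in the TPM total from a few abundant genes moves all others alike, so by itself it cannot lower some lists and raise others. Rescaling also moves all genes of a library alike, so it could not bring all these medians near 0 and was no separate test. After rescaling the medians were -2.02 for hypoxia and glycolysis, 1.66 for DNA replication and 1.41 for mitosis. An exchange of the titles between whole groups could not be decided from the Wnt targets, of which 9 were higher and 7 lower (7 and 7 after rescaling; two-sided exact binomial p = 0.804), and it cannot be told apart from the titles as given. A difference in culture, such as sphere size, oxygen, medium age or cell density on the day of harvest, may also give this pattern, and the design holds no sample that separates it from the treatment. The effect of the treatment named by the titles stays among the open explanations, untested.

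The third pattern is lower replication-dependent histone RNA beside higher replication genes, list calls that were also lost with an estimated correlation (adjusted p = 0.0896 and 0.0574). If reads of near-identical copies had only been moved between histone genes, their sum would not change, but the summed TPM of 59 genes was 2659 ± 55.0 in CON and 269 ± 8.33 in LF3 (log2 ratio -3.31, -3.38 to -3.24 over pairs of libraries). Fewer cycling cells would lower replication and mitosis genes too, and 0 called members of those lists were lower. The higher replication genes are part of the pattern itself, so this count restates it and is no independent test. A different capture of RNA without a poly(A) tail cannot be told apart, because the table held 0 tested RNAs of that kind other than histones; among histone genes known to give polyadenylated RNA, chosen after their values were seen, log2 fold changes were -1.22 ± 0.042 for H1-10 and -0.83 ± 0.037 for H2AJ on one side and 1.90 ± 0.048 for H2AZ1, 1.79 ± 0.055 for H2AX and 1.23 ± 0.036 for H2AZ2 on the other. The effect of the treatment named by the titles stays open here too, untested.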
